A study of Mus musculus with 4 samples.

How the data were processed

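Ring1b occupancy was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in C3H10T1/2 cells, a mouse embryonic mesenchymal progenitor line, that stably expressed FLAG-HA-tagged histone H3.3, either wild type (WT) or with the K36M substitution. Per the labels' protocols, the chromatin was fixed with formaldehyde, sonicated and incubated with a Ring1b antibody, and 5% was kept as input. The series has 4 libraries: 1 Ring1b library and 1 input library for each form of H3.3. Values of the 2 Ring1b libraries were used; values of the 2 input libraries were not analysed here.

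The authors deposited 1 table of 6371 genomic regions with a value for each Ring1b library. Per the submitters' processing notes, Bowtie 1.0.0 and the mouse build mm9 were used. The peak caller, its threshold, the treatment of duplicate reads and the counting rule are not given in the sources used here. The name of the table says that the regions are associated with peaks of the WT library, so that regions bound only in K36M cells would not be listed. All region borders are multiples of 200 bp, and a region that starts at 0 shows that starts are counted from 0; starts are printed here counted from 1.

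The deposited columns are headed RPKM (reads per kilobase and 1000000 reads), but the values behave as RPM (reads per 1000000 reads). All WT values are whole multiples of 0.0335 and all K36M values whole multiples of 0.0317, within a tolerance of 0.01 reads, whatever the width of the region. The value also rises with region width (Spearman's rho across regions 0.828 in WT and 0.739 in K36M). The deposited values are therefore called RPM here, that is, reads in a region scaled by 1 factor per library by the authors and not divided by the width. If the scale is exactly that, the steps imply depths of about 29850746 (WT) and 31545741 (K36M) reads; the steps have 3 digits, so the last digits of these depths carry no information. Dividing each value by its step gave whole reads per region, 1075510 in WT and 720528 in K36M over all regions, with medians of 139 and 91 reads per region. Ratios of the values themselves, and their counting intervals, do not depend on whether the values are divided by width; log2 ratios with a pseudocount do.

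With 1 library per form of H3.3 there is no replicate check, and no test of the difference between the forms was possible. The change of each region was described as log2((K36M + 0.1)/(WT + 0.1)) on the RPM scale, which understates the change of regions with low values. Counting error was given as the exact (Clopper-Pearson) 95% interval of the ratio of the 2 libraries, conditional on the total reads of the region. These intervals cover counting error only, and reads without molecular identifiers are not independent molecules. An exact two-sided binomial test on the reads with Benjamini-Hochberg adjustment at 0.05 was run as an added description; it compares these 2 libraries, not the forms of H3.3. Intervals of medians are order-statistic intervals over regions, which are not independent replicates. The interval was tested on simulated reads for the 6371 regions with 200 changed regions: it excluded a ratio of 1 on the right side for 80.6% of 1.5-fold, 86.6% of 2-fold and 100% of 4-fold changes, and on either side for 3.84% of unchanged regions. The simulated reads were independent Poisson counts, as the interval assumes. The simulation therefore checks the computation and the power at this depth, not duplicate reads or spread between libraries.

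Comparisons fixed before the data were examined were the change over all regions, the change in 5 equal bins of the mean of both libraries, and the rule for named items. That rule was written for genes and was applied to regions: the 8 lowest and the 8 highest log2 ratios among regions with a mean level at or above the median, and the 6 regions with the highest mean level. The rule did not say on which scale the mean is taken; the log2 scale, fixed for the bins, was used, and this was settled only when the rule was applied. Taking the mean of the RPM values instead, an alternative added after the data were seen, names 13 of the same 22 regions and replaces 9. The descriptions by width, by chromosome, by 1-Mb window, by dense run and by neighbouring region were chosen after the data were seen. A dense run was defined as at least 10 consecutive regions with gaps of at most 2000 bp. Windows with at least 5 regions were ranked by their median log2 ratio, and the 8 at each end were examined. Chromosome medians were set beside 10000 random sets of regions of the same size matched on mean level in 20 bins. Counts of windows were set beside 1000 shuffles of the log2 ratios among the regions of each chromosome.

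The table names no genes. The gene table available here is on the assembly GRCm38, a different build, and coordinates were not converted, so that no region is given a gene name and the 19 gene lists fixed beforehand were not used. Alternatives tried were pseudocounts of 0.01 and 1, leaving out the lower quartile of mean level, centring on the median, fold thresholds of 1.25 and 2, other binnings, and, after the data were seen, taking the mean of the RPM values for the named regions, leaving out the dense runs, merging regions within 2000 bp and calling by the counting interval. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.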

Results

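Ring1b, the catalytic ubiquitin ligase subunit of Polycomb repressive complex 1 (PRC1), was profiled by ChIP-seq in C3H10T1/2 mesenchymal progenitor cells expressing either WT H3.3 or H3.3K36M, in which the lysine that normally carries H3K36 methylation is replaced by methionine. The question was how the genome-wide distribution of Ring1b differs between these cells. The data comprised 6371 regions on 19 autosomes and the X chromosome, associated with Ring1b peaks of the WT library, with 1 library for each form of H3.3. The regions had a median width of 3000 bp (interquartile range 400 to 6800 bp) and together covered 29.1 Mb, leaving out 1 region that spans the first 3000400 bp of chromosome 11 with 26 WT and 38 K36M reads. Of them, 726 were 200 bp and 1180 were 400 bp wide. Values are RPM, with 1 read worth 0.0335 in WT and 0.0317 in K36M. With no replicates, no value below carries a between-culture error, and all intervals are 95% counting intervals unless stated otherwise.

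Ring1b levels were lower in K36M cells than in WT cells at 5422 of the 6371 WT-peak regions (85.1%) and higher at 948. The median region stood at 4.66 RPM in WT and 2.88 RPM in K36M. Values count all reads of a region, and background was not taken off. The median log2 ratio was -0.65 (order-statistic interval -0.68 to -0.63, quartiles -1.22 and -0.20), which is 36.4% lower. Summed over all regions, the values came to 36030 RPM in WT and 22841 RPM in K36M, or 3.60% and 2.28% of the reads if the scale is exactly reads per 1000000 reads. At least 1.5-fold lower levels were found at 3400 regions (53.4%), at least 2-fold lower levels at 2135 (33.5%) and at least 4-fold lower levels at 526 (8.26%). At least 1.5-fold higher levels were found at 78 regions (1.22%), at least 2-fold higher levels at 20, and at least 4-fold higher levels at 0. The ranking of regions was largely shared between the libraries (Spearman's rho 0.805 across regions, which are not independent replicates). Values are not divided by width and rise with it (rho 0.828 in WT and 0.739 in K36M), so that shared width can account for part of this.

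The difference exceeded counting error at most regions. The counting interval of the ratio lay wholly below 1 at 4145 regions (65.1%) and wholly above 1 at 195 (3.06%), and it included 1 at 2031. For a region of equal level in both libraries, chance gives at most 2.5% on each side. Most regions were lower, so that this share does not apply to all regions and does not show how many of the 195 reflect chance. The exact two-sided binomial test with Benjamini-Hochberg adjustment, which compares the 2 libraries and not the forms of H3.3, called 4062 regions lower and 179 higher. Because the regions were chosen in the WT library, a second library is expected to lie lower at them to an unknown extent. Centring the log2 ratios on their median, a shift of 0.65, left 3185 regions on each side, with 1557 at least 1.5-fold lower and 1127 at least 1.5-fold higher than the median region.

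**Figure D1:**
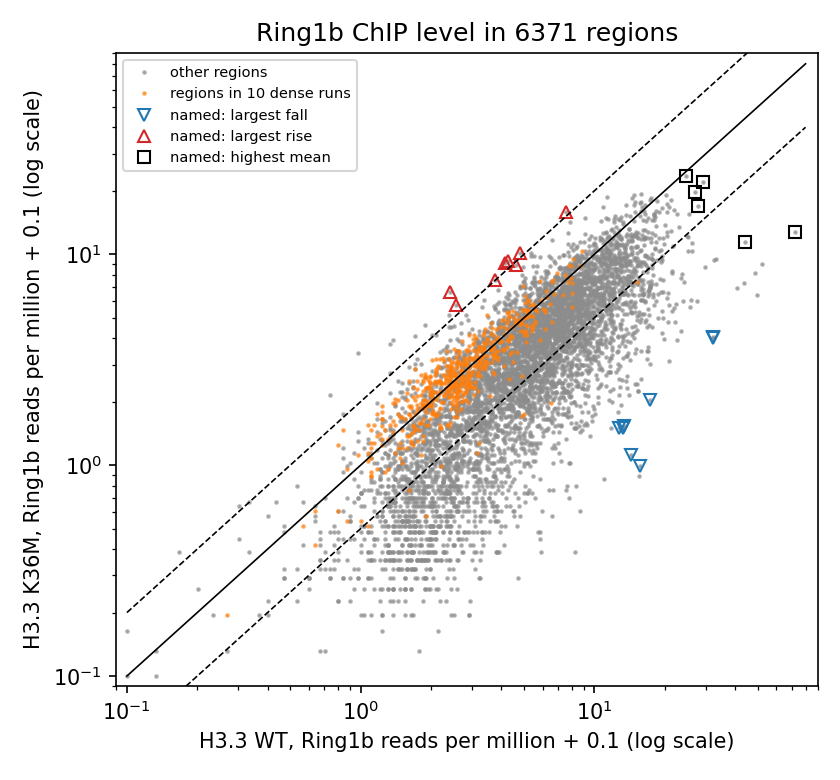
Ring1b level of each region in WT (x axis) and K36M cells (y axis), in RPM plus 0.1 on log scales; the solid line marks equality, the dashed lines 2-fold differences, orange points the regions in 10 dense runs and open symbols the 22 named regions. Most points, 5422 of 6371, lie below the solid line, whereas the orange points lie around it with a median log2 ratio of -0.00.

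The named regions below were ranked with the mean level taken on the log2 scale, a choice that affects which regions are named. The 8 largest reductions among regions of at least median level ranged from 8.11-fold to 17.5-fold. The largest was at chromosome 2, 146914001 to 146915200, where 15.5 RPM in WT stood against 0.888 RPM in K36M (463 and 28 reads), a 17.5-fold lower level with an interval of 11.9-fold to 26.6-fold. The region at chromosome 6, 54287001 to 54289000, held 14.2 RPM in WT and 1.01 RPM in K36M (interval 9.74-fold to 20.7-fold lower). The region at chromosome 1, 55948401 to 55952600, was 9.42-fold lower (13.1 against 1.39 RPM), and the region at chromosome 2, 94036001 to 94037600, was 9.30-fold lower (13.3 against 1.43 RPM). At chromosome 11, 111607201 to 111610200, the level was 9.03-fold lower, and at chromosome 9, 31713801 to 31721800, it was 8.90-fold lower. Chromosome 14, 104857401 to 104864400, and chromosome 2, 73612401 to 73616000, had the highest WT values of the 8 (32.0 and 32.1 RPM, not divided by width). They were 8.21-fold and 8.11-fold lower in K36M (3.90 and 3.96 RPM, from 123 and 125 reads). Their WT densities, 4.57 and 8.92 RPM per kb, were below the 12.9 of the region at chromosome 2, 146914001. With the mean taken on the RPM values instead, 6 of these 8 regions were replaced, and the largest reduction was at chromosome 5, 49728601 to 49729000, with 8.17 RPM in WT and 0.285 RPM in K36M (244 and 9 reads, 28.7-fold lower, interval 14.8 to 63.4).

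The 8 largest increases were smaller, from 1.94-fold to 2.83-fold. The highest was at chromosome 12, 114261401 to 114262200, an 800-bp region with 2.31 RPM in WT and 6.53 RPM in K36M (2.83-fold, interval 2.14 to 3.77). A 400-bp region at chromosome 19, 36203801 to 36204200, was 2.31-fold higher (interval 1.75 to 3.07). The other 6 were 2400 to 5800 bp wide. Among them, chromosome 6, 17158601 to 17163200, had the highest level not divided by width, with 7.44 RPM in WT and 15.8 RPM in K36M (2.13-fold, with at least 1.81-fold by the lower bound of its interval). Per kb it held 1.62 and 3.44 RPM, below the 1.69 and 3.75 at chromosome 18, 69862401. Chromosome 18, 69862401 to 69864800, was 2.22-fold higher, chromosome X, 163417801 to 163423600, 2.21-fold, chromosome 3, 107508401 to 107511800, 2.11-fold, chromosome 18, 61049801 to 61052200, 2.04-fold, and chromosome 13, 63217801 to 63221200, 1.94-fold, each with an interval above 1. All 8 were also named with the mean of the RPM values. Of the 3186 regions of at least median level, 1433 were at least 1.5-fold lower and 33 at least 1.5-fold higher.

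The 6 regions with the highest mean level differed widely in their change. Levels are not divided by width, so that wide regions can rank high at a modest density. The region with the highest WT value, chromosome 14, 122877201 to 122899000 (21800 bp), held 72.0 RPM in WT and 12.6 RPM in K36M, a 5.70-fold lower level (interval 5.12 to 6.36). Chromosome 2, 110017401 to 110028800, was 3.91-fold lower (44.2 against 11.3 RPM, interval 3.48 to 4.41). Chromosome 7, 75404401 to 75412000, was 1.65-fold lower (27.7 against 16.8 RPM, interval 1.47 to 1.84). The ratio was closer to 1 at chromosome 18, 52686601 to 52696800, which was 1.37-fold lower, and at chromosome 5, 150174201 to 150189400, which was 1.33-fold lower; relative to the median region both were higher, by 0.20 and 0.24 on the log2 scale. At chromosome 14, 23621001 to 23659600, the level was 24.5 RPM in WT and 23.4 RPM in K36M, a ratio of 0.954 whose interval of 0.860 to 1.06 includes 1, and which lay 0.59 above the median region on the log2 scale. Ranking by the mean of the RPM values replaced 3 of the 6, those on chromosomes 7 and 18 and the nearly equal one on chromosome 14, by regions with much lower K36M levels: chromosome 1, 14293801 to 14304600 (52.2 against 8.88 RPM, 5.88-fold lower), chromosome 6, 51131601 to 51149400 (48.4 against 8.05 RPM, 6.01-fold lower), and chromosome 12, 73997201 to 74010800 (49.4 against 6.34 RPM, 7.80-fold lower).

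The median log2 ratio was below 0 in all 5 equal bins of mean level. Levels are not divided by width, and the median width rose from 400 bp in the lowest bin to 10600 bp in the highest. The bins therefore do not separate level from width. The median log2 ratio was -1.33 in the lowest bin (median 1.64 RPM in WT and 0.602 RPM in K36M), then -0.58, -0.63, -0.53, and -0.46 in the highest bin (10.8 and 7.39 RPM). Relative to the median region, the lowest bin stood at -0.67 and the other 4 between 0.02 and 0.20. The difference between the highest and the lowest bin depended on the binning. It was 0.87 for bins of the mean of both libraries, -0.01 for bins of the WT value and 1.32 for bins of the K36M value, so that no trend with level is stated.

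Regions of 400 to 2000 bp had lower ratios than wider ones, and regions of 200 bp lay among the wider classes. Outside dense runs of regions, the median log2 ratio was -1.17 for the 1051 regions of 400 bp (order-statistic interval -1.27 to -1.09), -0.98 for the 460 regions of 1200 to 2000 bp, -0.64 for the 1426 regions of 4200 to 8000 bp and -0.47 for the 254 regions wider than 16000 bp (interval -0.52 to -0.40). At least 2-fold lower levels were found at 57.4% of the 400-bp regions and at 12.6% of those wider than 16000 bp. Read density differed between these classes. The 400-bp regions had a median of 5.11 RPM per kb in WT and 1.98 in K36M, and the regions wider than 16000 bp had 0.601 and 0.419. Values include background reads, whose level is unknown because input values were not analysed. At a low density such reads can limit the fold. The ratios of the widest class therefore do not show how much Ring1b it kept. The 356 regions of 200 bp stood at -0.60 (interval -0.78 to -0.43), between the -0.64 of the 4200 to 8000 bp class and the -0.47 of the widest class, and 39.0% of them were at least 2-fold lower. Relative to the median of all regions, dense runs included, the 200-bp class lay at 0.05, the 400-bp class at -0.52 and the widest class at 0.19. The median outside runs was lower, at -0.74, so that all classes would lie higher against it. Over all regions the difference between these classes was 0.57, and it was 0.18 with a pseudocount of 1.

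**Figure D2:**
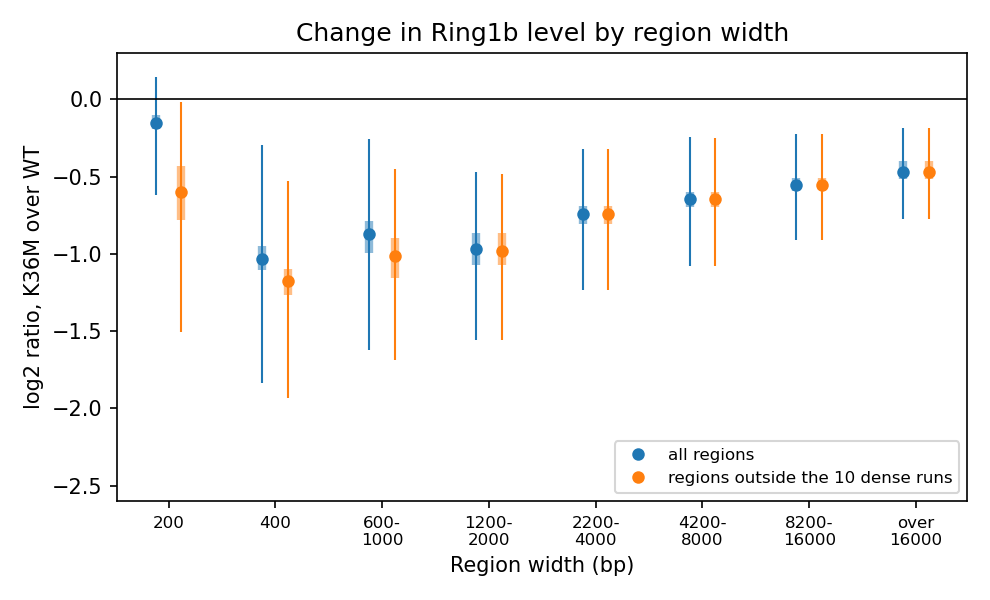
Log2 ratio of K36M over WT (y axis) by region width in bp (x axis), for all regions (blue) and for regions outside the 10 dense runs (orange); points are medians, thick bars 95% order-statistic intervals and thin bars quartiles. Outside the runs the median moves from -1.17 at 400 bp to -0.47 above 16000 bp, and the class of 200 bp moves from -0.15 to -0.60 when the runs are left out.

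Dense runs of regions had nearly equal levels in both libraries. The table held 10 runs of at least 10 consecutive regions, with 558 regions in all (8.76%), and their median log2 ratio was -0.00 against -0.74 for the 5813 other regions. In 9 of the runs, on chromosomes 5, 8, 11 and 17, run medians lay between -0.24 and 0.26, with 4.16 to 10.6 RPM per kb in WT. Most of their regions were 200 or 400 bp wide, and regions of those widths outside runs had medians of 7.45 and 5.11 RPM per kb in WT and 3.96 and 1.98 in K36M. In WT, 7 of the 9 runs lay above both medians, and in K36M all 9 did. The largest held 194 regions at chromosome 8, 19917401 to 19987000 (537 RPM in WT and 571 RPM in K36M). The remaining run, 10 regions at chromosome 11, 96051001 to 96067400, was 2.55-fold lower in K36M (43.7 against 17.1 RPM), with all 10 counting intervals below 1.

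Regions with similar ratios were grouped along the chromosomes. Of 445 windows of 1 Mb with at least 5 regions, 243 had every region lower in K36M, against 149 to 199 when the log2 ratios were shuffled 1000 times among the regions of each chromosome. The median was at or below -1 in 145 windows (71 to 118 when shuffled), at or below -2 in 13 (0 to 5) and above 0 in 20 (1 to 16). The 425 windows with a median below 0 were fewer than the 429 to 444 of the shuffles. Windows often hold touching regions, which shuffling parts. The lowest window was chromosome 2, 94 to 95 Mb, with 15 regions summing to 126 RPM in WT and 19.2 RPM in K36M, 6.56-fold lower (interval 6.02 to 7.16). In it, 14 regions between 94014601 and 94105600 had log2 ratios from -3.67 to -1.69, and a single 400-bp region at 94959601 stood at -0.21. The windows at chromosome 2, 146 to 147 Mb, and chromosome 2, 73 to 74 Mb, were 6.93-fold and 6.31-fold lower. All 7 and all 8 of their counting intervals lay below 1. Most regions of these chromosome 2 windows touched another region, so that their intervals do not count separate sites. The windows also hold largest reductions named above, those at 94036001, 146914001 and 73612401, and are not further loci. The window at chromosome 4, 116 to 117 Mb, was 4.85-fold lower over 8 regions. That at chromosome 3, 96 to 97 Mb, was 4.12-fold lower over 22 regions, of which 21 had intervals below 1. Most of these 22 regions also touched another region. In the window at chromosome 4, 79 to 80 Mb, every region was higher in K36M: 6 regions of 200 bp, within 79648601 to 79650200, summed to 15.9 RPM in WT and 26.1 RPM in K36M, 1.63-fold higher (interval 1.46 to 1.83), and 3 of the 6 counting intervals lay above 1. Each of the 6 touched another of them. Most reads of this window lay in the regions at 79648801 and 79649801, with 37.9 and 27.1 RPM per kb in WT. The WT median of 200-bp regions outside runs was 7.45. Whether reads pile up there without Ring1b was not tested, since input values were not analysed. The window at chromosome 4, 89 to 90 Mb, was 1.49-fold higher over 6 regions, of which 2 had intervals above 1. The window at chromosome 11, 109 to 110 Mb, had the next highest median (0.31), but its summed ratio of 1.07 had an interval of 0.952 to 1.21 that includes 1. That at chromosome 5, 91 to 92 Mb, was 1.31-fold higher over 5, of which 2 had intervals above 1 and 1 below.

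**Figure D3:**
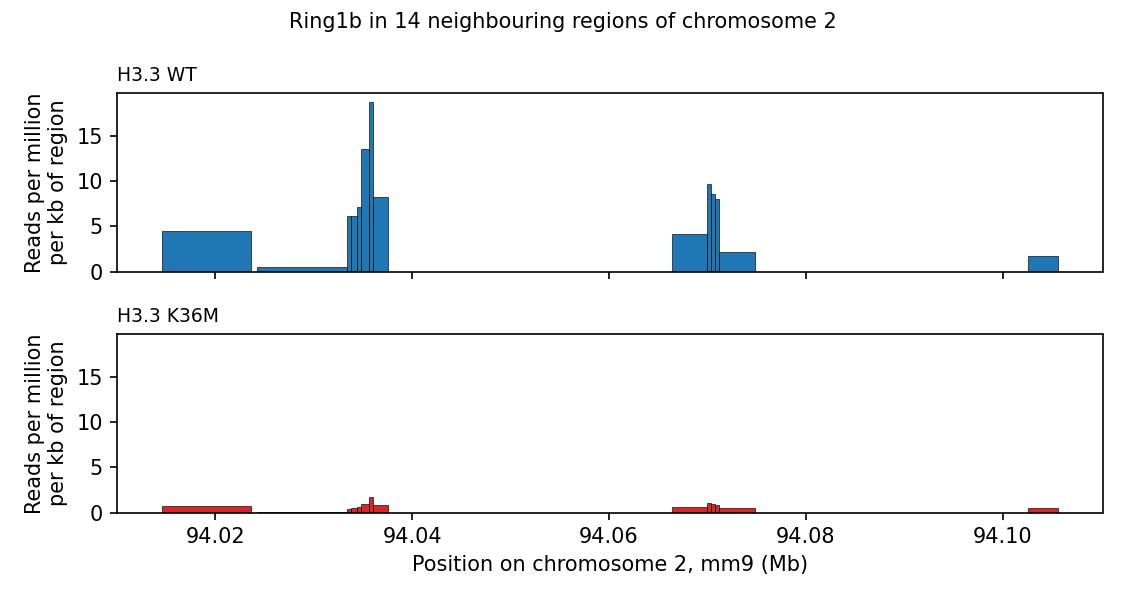
Ring1b density in WT (upper) and K36M cells (lower), in RPM per kb of region (y axes, same scale), at 14 regions of chromosome 2 by mm9 position in Mb (x axis); each bar spans 1 region, and blank stretches are positions outside the listed regions, not measured zeros. The highest bar is 18.8 RPM per kb in WT and 1.74 in K36M.

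Neighbouring regions had similar log2 ratios. After the median of each chromosome was removed and the dense runs were left out, Spearman's rho between the log2 ratios of neighbours was 0.71 for 1102 touching pairs (Pearson's r 0.67), 0.58 for 392 pairs with gaps over 2 and up to 10 kb, 0.38 for 870 pairs with gaps over 10 and up to 50 kb (Pearson's r 0.37), 0.23 for 1135 pairs up to 200 kb and 0.06 for 1285 pairs up to 1000 kb. In 1000 shuffles within chromosomes, the highest rho for gaps over 10 and up to 50 kb was 0.11. These are correlations across regions of the same 2 libraries, 6 in this family.

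**Figure D4:**
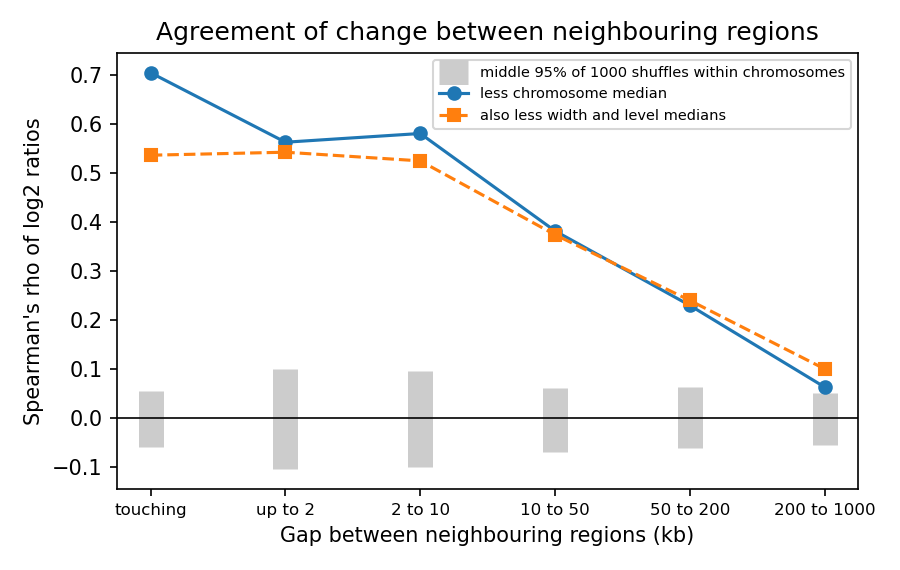
Spearman's rho between the log2 ratios of neighbouring regions (y axis) by the gap between them in kb (x axis), after the chromosome medians were removed (blue) and after the medians of width class and level bin were also removed (orange); grey bars hold the middle 95% of 1000 shuffles. Both lines start above 0.5 for touching regions and reach 0.06 and 0.10 at gaps of 200 to 1000 kb.

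Every chromosome had a negative median log2 ratio. Outside the dense runs, chromosome 14 had the lowest median (-1.06, order-statistic interval -1.19 to -0.99, 234 regions), with 97.0% of its regions lower in K36M and 56.4% at least 2-fold lower. Chromosome 5 had the highest median (-0.36, interval -0.50 to -0.26, 239 regions), with 79.1% of its regions lower and 21.8% at least 2-fold lower. The X chromosome stood at -0.45 on 74 regions. Of the 20 chromosomes, 3 lay within the lowest 2.5% of random sets matched on level and 7 within the highest 2.5%. Random sets break up the local grouping of changes, so these percentiles describe the 2 libraries and overstate how far a chromosome stands apart. Relative to the median region, chromosomes 5, 8, 11, 13, 17, 18 and X lay above 0 when all regions were counted. For chromosomes 8 and 11 the size of this offset depended on the dense runs: their medians were -0.18 and -0.31 with the runs and -0.65 and -0.60 without them, when the median over all regions outside runs was -0.74.

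**Figure D5:**
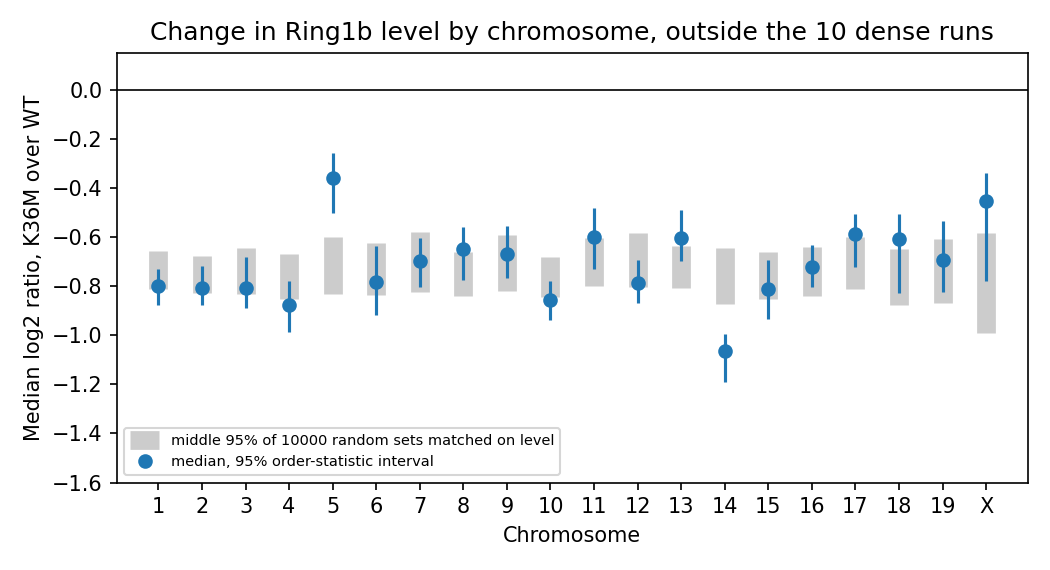
Median log2 ratio of K36M over WT (y axis) for each chromosome (x axis), outside the 10 dense runs; blue points and bars are medians with 95% order-statistic intervals and grey bars the middle 95% of 10000 random sets matched on level. All medians lie below 0, from -1.06 on chromosome 14 to -0.36 on chromosome 5.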

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

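Leaving out dense runs, merging regions, calling by counting interval, naming by the mean of the RPM values, and all alternatives on width, neighbours, windows and chromosomes were chosen after the data were seen. The negative median log2 ratio kept its sign under every alternative except centring, which sets it to 0: it was -0.51 with a pseudocount of 1, -0.54 without the lower quartile of mean level, -0.74 without the dense runs and -0.69 with regions within 2000 bp merged. A pseudocount of 1 pulls low values toward 0 by construction and the dense runs hold nearly equal values; for merging, the cause was not tested. Centring gave 3185 regions lower and 3185 higher, 1557 at least 1.5-fold lower and 1127 at least 1.5-fold higher. The 3400 regions at least 1.5-fold lower became 2240 without the lower quartile and 2135 at a threshold of 2-fold. The 2240 come partly from fewer regions. The lowest of the 5 bins of mean level also had 77.2% at least 1.5-fold lower, against 53.4% of all regions. A low K36M value itself helps to place a region in that bin. With bins of the WT value, the lowest and the highest bin had medians of -0.776 and -0.781, so that no trend with level is stated. The 78 regions at least 1.5-fold higher became 43 with a pseudocount of 1, 43 after merging, 20 at 2-fold, 273 at the lower of the alternative thresholds and 195 when called by the counting interval, and merging left 474 units higher. The difference between the top and bottom level bins, 0.87, was 0.26 with a pseudocount of 1 and 1.13 with 10 bins. It was 1.32 with bins of the K36M value and -0.0053, a reversal, with bins of the WT value. A bin chosen on one library carries that library's own deviations, which may contribute to the reversal. How much they contribute was not tested. The difference between regions wider than 16000 bp and regions of 400 bp, 0.57, was 0.18 with a pseudocount of 1 and 0.71 without the dense runs. Under centring, 3 named regions turned positive, at 0.24 (chromosome 5, 150174201), 0.59 (chromosome 14, 23621001) and 0.20 (chromosome 18, 52686601), as did chromosomes 5 (0.39), 8 (0.47), 11 (0.34), 13 (0.0503), 17 (0.0885), 18 (0.0462) and X (0.20). Centring also turned positive the level bins above the lowest (0.02 to 0.20) and, outside runs, the width class of 200 bp and those over 4000 bp (0.01 to 0.19). The width classes outside runs were centred on the median of all regions, dense runs included. Spearman's rho of neighbours at gaps over 10 and up to 50 kb, 0.38, lay between 0.37 and 0.42 under the 3 alternatives tried. Without the dense runs, the median of chromosome 8 moved from -0.18 to -0.65 and that of chromosome 11 from -0.31 to -0.60, so that the size of their positive centred values depends on the runs. All 22 named regions kept their log2 ratio within the counting interval with a pseudocount of 0.01, and 14 did so with a pseudocount of 1. With the mean of the RPM values, 13 of the 22 were named again: all 8 rises, 3 of the 6 highest and 2 of the 8 reductions. The replaced reductions gave way to regions with fewer K36M reads, since a plain mean admits a region on its WT value alone. The alternatives that need gene names (the fixed gene lists, and every row or the mean of a gene's rows) and the correction by input were not run. No paired analysis was possible because each form of H3.3 has 1 library. Depth limits the narrow regions most: the 400-bp regions outside runs had a median of 25 reads in K36M, and 233 regions had fewer than 10. In WT, 17 of the listed regions had fewer than 10 reads and 2 had 0.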

Other observations

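All tests of explanations below except that on shared width and level were chosen after the result was seen. Narrow regions beside wider ones had lower ratios than those neighbours in most cases. Outside dense runs, 829 regions of 200 or 400 bp belonged to chains, with gaps of at most 2000 bp, that held a wider region, and their median log2 ratio was -1.24 against -0.70 for the widest region of the chain; 621 of them (74.9%) had a lower ratio than that region. The 578 narrow regions with no wider partner stood at -0.82. The widths differed: 200-bp regions stood at -0.97 beside a wider region and -0.39 without one, and 400-bp regions at -1.29 and -1.003. Among 256 regions wider than 1000 bp with a mean density of at least 2 RPM per kb, the middle of the distribution ran from -1.24 to -0.11 (quartiles), so that densely bound regions included both much lower and nearly equal ones.

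The first pattern is the general reduction in K36M cells. A wrong scaling of one library would lower all regions alike, and it is argued against by the 558 regions in dense runs, whose median log2 ratio was -0.0006; those runs may be places where reads pile up without Ring1b, and input values were not analysed here. Counting noise in regions chosen in the WT library is argued against by the 1448 regions with at least 200 reads on average, whose median was -0.516. Whether one lower enrichment for every region accounts for the differences between regions stays open: 72.3% of the 256 densely bound regions had a counting interval off their common ratio of 0.629, but no pair of libraries of the same form shows how far libraries differ beyond counting error. As the source of the general reduction itself, a less efficient immunoprecipitation and an effect of H3.3K36M cannot be told apart, because there is 1 library per form of H3.3, and variation between cultures other than counting noise also stays open.

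The second pattern is the lower ratio of 400-bp regions than of wide ones; the median of 200-bp regions outside runs, -0.60 (interval -0.78 to -0.43), was not clearly apart from that of the widest class, -0.47 (-0.52 to -0.40). Counting noise in regions chosen in the WT library stays open: Spearman's rho between narrow regions and the widest region of their chain was 0.728 across 829 pairs, some with the same wide partner, but such noise would lower all narrow regions and leave rho as it is. Dilution by background reads is argued against as the whole source only for the densest regions wider than 8000 bp (304 regions). Taking off 0.419 RPM per kb from both libraries moved their gap to 400-bp regions from 0.72 to 0.780 (-0.78 and -1.56 afterwards). For wide regions in general, dilution stays open. The 0.419 is the median K36M density of regions wider than 16000 bp, whose WT median was 0.601. Taking it off leaves no excess at their K36M median, so that the step cannot decide for them. It also stays open whether narrow regions were listed for a high WT density, since the listing rule is not given. Outside runs their WT medians were 7.45 (200 bp) and 5.11 (400 bp) RPM per kb, but a 200-bp region at chromosome 4, 79650001, held 0.50. Duplicate reads in the WT library also stay open, since they cannot be examined in this table. A biological explanation, that Ring1b was reduced most at focal sites, was not tested.

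The third pattern is the similarity of neighbouring regions. Single peaks split into pieces are argued against as the whole source by a rho of 0.383 at gaps over 10 and up to 50 kb, and copy number or other differences over segments much longer than 1000 kb, as the whole source, by a rho of 0.064 at gaps over 200 and up to 1000 kb. That rho lay just above the middle 95% of shuffles (-0.05 to 0.05) and was 0.10 after width and level were removed, so that a small part from long segments, and a larger part from shorter ones, stay open; differences between whole chromosomes had been removed beforehand. Neighbours of similar width and level are argued against by a rho of 0.375 at gaps over 10 and up to 50 kb after the medians of width class and level bin were removed. With 1 library per form of H3.3, the similarity may reflect regional differences between any pair of libraries, and no biological explanation was tested; it also did not end at 50 kb, with a rho of 0.23 at gaps over 50 and up to 200 kb (highest of 1000 shuffles 0.11).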
